A study of Mus musculus with 5 samples.

How the data were processed

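Single-cell RNA was measured in 5 libraries of sorted Lin-Sca1+Kit+ (LSK) mouse cells, made per the labels' protocols with a 10x Genomics 5' kit and sequenced on an Illumina NovaSeq. Per the labels, the cells came from a pool of 5 mice per arm 12 weeks after transplantation, were sorted on BFP or RFP as the sign of sgRNA transduction, and numbered 10000 per sample. The deposited matrices hold the authors' counts, which are raw UMI counts per gene and barcode from Cell Ranger 7.1.0, per the file headers, without normalisation and without a cell filter. The deposited barcode and feature lists hold names in the order of the matrix columns and rows, with 32285 genes. The submitters' processing notes name the mm10 build and Seurat 3, and no file made with Seurat was among those used here. Whether intronic reads were counted and which annotation release was used are not given in the sources used here.

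A barcode was kept as a cell if its UMIs reached 10% of the 99th percentile of the 5000 largest barcodes of its library (minimum 2356 to 4536 UMIs), with at least 500 genes and under 10% mitochondrial UMIs. This kept 11480 cells, with 20288820 to 46617350 UMIs per library and medians of 7692 to 14682 per cell. Pairs of libraries shared 5 to 10 cell barcodes, against 4.78 to 10.6 expected by chance. Scrublet marked 13 cells as doublets, under the 0.5% at which they were to be removed, so they were kept. Estimated free RNA made up 0.684% to 3.596% of cell UMIs with the profile of barcodes with 10 to 100 UMIs, and 1.90% to 9.32% with that of barcodes ranked 10000 to 50000.

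All libraries were clustered together with Scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours) and leidenalg 0.10.2 at resolution 1.0, which gave 21 clusters. Genes of the lists other than cell type markers, and Ncoa4, Tet2, cell cycle, sex-linked, mitochondrial, ribosomal, haemoglobin and antigen receptor genes, took no part. A cluster was named after the marker set with the most of its 10 leading genes by fold (pseudocount 5), if at least 2 of these and at least 3 detected genes belonged to the set. The first marker among the leading genes also had to belong to it, and no tied set could hold more detected genes, or the cluster stayed unnamed. Under this rule 10 clusters were named and 11 were not. Among the unnamed, a cluster of 517 cells was led by the mast cell or basophil genes Prss34, Fcer1a and Ms4a2 beside Pf4 and Gata1, and a cluster of 316 cells by Prg2, Cpa3 and Mcpt8 beside Ctsg and Mpo. No cluster took the name of mast cells or basophils, eosinophil progenitors, B cells, plasma cells, erythroblasts or endothelial or stromal cells. The early progenitor grouping of 6 clusters was defined after the data were seen.

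For each library, UMIs were summed over cells and scaled to counts-per-million (CPM), the 2 Tet2 KO control libraries being averaged with equal weight. Log2 ratios are of CPM plus 1. Folds in the text are ratios of pooled UMI shares with exact conditional binomial 95% intervals, and cell shares have Clopper-Pearson 95% intervals. Where a group had no UMI, the fold is a lower bound against 3 counts over the group. No test was made, since 3 of the 4 groups had 1 library and the labels do not say whether the 2 Tet2 KO control libraries are separate pools, and a size rule took its place: at least 20 CPM and 50 UMIs in a group and at least 1.5-fold, in the same direction against each Tet2 KO control library where these were used. The 4 comparisons were Ncoa4 against control sgRNA in Tet2 KO and in WT, and Tet2 KO against WT under either sgRNA. The difference of the log2 ratios between genotypes was also taken per gene, and counted from 1 log2 unit on for genes past the rule in either genotype.

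Named genes were, in each comparison, the 12 most higher and 12 most lower past the size rule, leaving out gene models and mitochondrial, ribosomal, antigen receptor, haemoglobin and sex-linked genes. Ncoa4, Tet2, Fth1, Ftl1, Tfrc, Slc40a1, Hmox1, Slc25a37, Iscu and Gpx4 were always named, with the 2 most higher and 2 most lower members of each gene list at 20 CPM or more. The 6 most positive and 6 most negative differences of effects were named, and sex-linked genes were given once as a check of the pools. The rule was also applied within the myeloid progenitor-like class and, by a later choice, within the early progenitor clusters. Some genes that the rule gives are not reported here. Each of 23 gene lists was scored by its median log2 ratio over members with at least 50 UMIs, minus the median over 10000 random lists of the same size matched on expression in 25 bins. A list in the outer 2.5% of the random lists on either side counts as past the limits. Alternatives used 2000 random lists.

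The rule was tried on data simulated from these libraries, with 6742 to 7412 genes per comparison. It called 98.5% to 100% of planted 2-fold and 4-fold changes, 0 of 68 smaller ones, under its size, and 0 unchanged genes. Lists of 30 genes with the smaller change reached percentile 100 throughout, and unchanged lists 8.58 to 33.4. Ratio intervals covered the true value in 95.3% to 97.05% of 2000 pairs. These checks cover counting error only, since the same-label Tet2 KO control libraries had 324 genes past the rule.

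The cell rule, size rule, gene lists, marker sets, named-gene rule and alternatives were fixed before the data were examined, except where a choice is said to have been made later. The alternatives moved the cell minimum (raised 2-fold, lowered by 50% but to no fewer than 500 UMIs), the mitochondrial limit (5%), doublet removal, free RNA subtraction, scaling (TMM of edgeR 4.0.16 in R 4.3.3, and totals without mitochondrial and ribosomal genes), depth (cells thinned to 3000 UMIs, which left out 98 WT control cells), averaging over cells, class weights of WT control (over 17 of 19 classes), the CPM filter (5, 50 or none), the pseudocount (5), each Tet2 KO control library and the clustering (resolution 0.5 and 1.5, 20 principal components). Others were added after the data were seen: single groups of clusters, removal of neutrophil-like and macrophage-like clusters, another free RNA profile, removal of the top 2% of doublet scores, and removal of the trend with GC content. The HSC-like class, with 14 cells in Tet2 KO Ncoa4, was too small for gene comparisons and was left out of them. Positions are from GENCODE M21 on GRCm38. Tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9.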

Results

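Blood stem and progenitor cells of mice were profiled by single-cell RNA sequencing of transcript 5' ends in 4 groups. The cells were wild type (WT) or Tet2 knockout (Tet2 KO), carried the nuclease Cas9, and had been transduced with a non-targeting control sgRNA or with sgRNA against Ncoa4. Ncoa4 encodes the receptor that takes ferritin, the iron store of the cell, to the lysosome for iron release, and Tet2 encodes an iron-dependent enzyme that oxidises methylated cytosine in DNA. Per the labels' protocols, the transduced cells were transplanted, and marker-positive cells of the LSK gate (lineage-negative, Sca1-positive, Kit-positive, the gate for stem cells and multipotent progenitors) were sorted after 12 weeks from a pool of 5 mice. The series title poses the question of whether blood formation without Tet2 depends on Ncoa4-driven ferritin turnover.

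WT control, WT Ncoa4 and Tet2 KO Ncoa4 sgRNA had 1 library each, and Tet2 KO control sgRNA had 2, which the labels do not assign to separate pools. With 1 library in 3 of the 4 groups no test was made, and the intervals given cover counting error only. The difference between the 2 Tet2 KO control libraries served as the yardstick. The libraries held 2227, 2959, 2570, 2048 and 1676 cells for WT control, WT Ncoa4, Tet2 KO control 1, Tet2 KO control 2 and Tet2 KO Ncoa4. In the same order, their cells held 20288820, 46617350, 33062134, 36054373 and 22234250 unique molecular identifiers (UMIs), with medians of 7692, 14462, 11138.5, 14682 and 11919.5 per cell. Levels are counts-per-million (CPM) of UMIs summed over cells. A fold is the ratio of UMI shares between groups with its exact 95% interval.

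Xist, which is transcribed from the inactive X chromosome, reached at most 0.135 CPM in any group, and Y-linked Ddx3y lay between 26.1 and 44.6 CPM.

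The first question was which cells each library held. Neutrophil-like cells, marked by the granule genes Camp, Ltf and Lcn2 and the calprotectin genes S100a8 and S100a9, made up 29.9% (27.7 to 32.1) of cells in Tet2 KO Ncoa4 and 9.97% (8.91 to 11.1) in WT Ncoa4 (Clopper-Pearson intervals). Under control sgRNA they numbered 0 of 2227 cells in WT, with an upper limit of 0.166%, and 1 of 2570 and 0 of 2048 in the Tet2 KO libraries, where the upper limit for the 0 is 0.180%. Myeloid progenitor-like cells, which express the primary granule genes Mpo, Elane and Prtn3, made up 29.1% (26.9 to 31.3) in Tet2 KO Ncoa4 against 4.32% and 4.004% in the Tet2 KO controls, and 20.6% (19.2 to 22.1) in WT Ncoa4 against 8.17% (7.07 to 9.39) in WT control.

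Early progenitor clusters, picked by Ly6a (which encodes Sca1) and Cd34 transcripts above their level over all cells, showed the opposite difference. They made up 6.03% (4.93 to 7.27) of cells in Tet2 KO Ncoa4 against 64.2% (62.3 to 66.0) and 66.8% (64.8 to 68.9) in the controls, and 23.2% (21.7 to 24.7) in WT Ncoa4 against 51.9% (49.8 to 54.0) in WT control. Chosen after the data were seen, these 6 clusters differed in mix between libraries. A cluster led by Cdk8 and Filip1l held 27 of the 101 early cells of Tet2 KO Ncoa4, against 43 of 1649 and 37 of 1369 in its controls, and 293 of 686 in WT Ncoa4 against 23 of 1155 in WT control. HSC-like cells made up 14 of the early cells of Tet2 KO Ncoa4 against 358 and 460, and 29 of WT Ncoa4 against 166. Values given within the early clusters carry this difference in mix. Lymphoid-primed progenitor-like cells, with Flt3 and Dntt, made up 0.776% against 5.72% and 6.40% in Tet2 KO, and 1.35% against 7.05% in WT. HSC-like cells, with Procr and Hlf, made up 0.835% against 13.9% and 22.5% in Tet2 KO. Leaving out the 13 marked doublets before clustering moved these shares to 0.658% against 6.74% and 9.42%, and that of WT control to 0.809%. In WT they made up 0.980% against 7.45%, a direction that turned at clustering resolution 0.5 (7.71% against 4.63%) and with a mitochondrial share under 5% (7.53% against 2.24%).

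An unnamed cluster with the monocyte genes F13a1, Csf1r and Ccr2 made up 16.6% in Tet2 KO Ncoa4 against 5.84% and 4.54%, and 15.2% in WT Ncoa4 against 4.80%. Macrophage-like cells, with the complement genes C1qa, C1qb and C1qc, numbered 60 of 1676 and 60 of 2959 under Ncoa4 sgRNA and 3 in every control library. The leading genes of this cluster also held the neutrophil genes Ngp and Camp, with S100a8 at 44886 CPM and a median of 23708 UMIs per cell, the highest of all clusters. Clusters with a median mitochondrial share over 3%, a limit chosen after their values were seen, held 24.7% of WT control, 17.2% of WT Ncoa4, 17.7% and 9.91% of Tet2 KO control and 6.26% of Tet2 KO Ncoa4 cells. Over all cells, transcripts of the sort markers Ly6a and Kit stood at 14.1 against 45.7 CPM and 103 against 314 CPM for Ncoa4 against control sgRNA in Tet2 KO, and at 19.7 against 38.1 CPM and 215 against 356 CPM in WT.

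**Figure D1:**
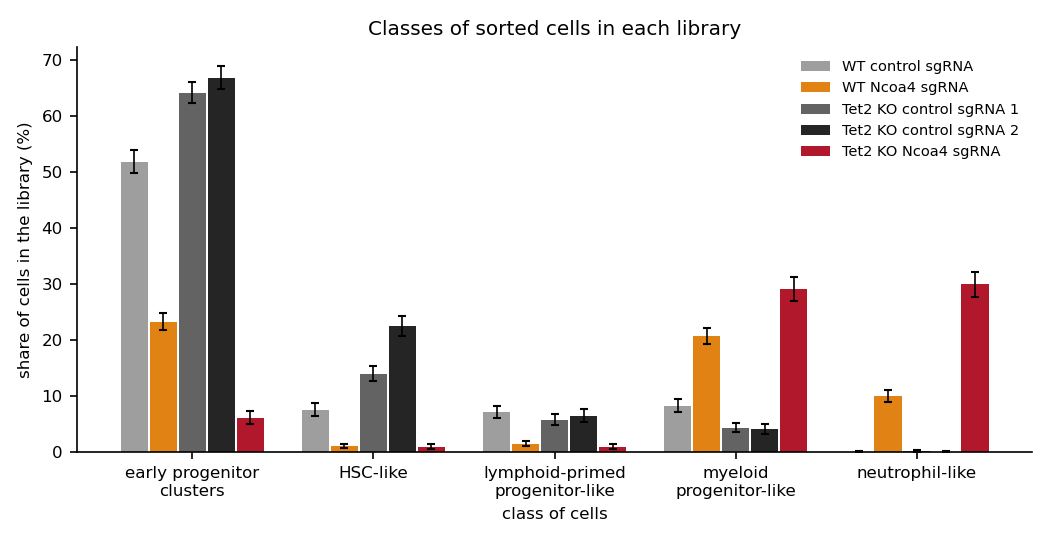
Share of cells per class (y axis, percent of the cells of a library) in each of the 5 libraries, with error bars for exact 95% intervals of counting error. Neutrophil-like cells reach 29.9% and 9.97% under Ncoa4 sgRNA, and the early progenitor clusters 6.03% and 23.2%.

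Ncoa4 sgRNA was compared with control sgRNA in Tet2 KO cells to ask how targeting the ferritin receptor changed progenitors that lack Tet2. Ncoa4 (ENSMUSG00000056234, chromosome 14, 32159865 to 32179855, GRCm38) was 2.52-fold lower (95% interval 2.37 to 2.68), at 51.8 against 131 CPM, and lower in 11 of 11 clusters with at least 20 cells on each side. Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794), the transferrin receptor that takes up iron, was 2.45-fold higher (95% interval 2.28 to 2.63), at 60.6 against 24.9 CPM, and higher in 11 of 11 clusters. Fth1 (ENSMUSG00000024661, chromosome 19, 9980598 to 9985098), the ferritin heavy chain, was 1.77-fold lower (95% interval 1.74 to 1.79), at 1139 against 2012 CPM, and lower in 10 of 11 clusters. Slc40a1 (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523), the iron exporter ferroportin, was 7.87-fold higher (95% interval 6.97 to 8.91), at 41.9 against 5.33 CPM.

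Within the early progenitor clusters, Ncoa4 stood at 62.4 against 139 CPM, Tfrc at 65.6 against 13.9 CPM and Fth1 at 1712 against 2282 CPM. The myeloid progenitor-like class joined 2 clusters, the first with 379 of 487 cells in Tet2 KO Ncoa4 and 60 of 111 and 32 of 82 in the controls. In the first and the other, the ratio of Tfrc was 1.75 (1.26 to 2.47) and 3.10 (2.27 to 4.28), and that of Slc40a1 3.20 (2.20 to 4.81) and 2.19 (0.957 to 5.30). Slc40a1 had a log2 ratio of 0.08 in the early clusters, with 2 UMIs in the Ncoa4 arm, and 2.06 without the neutrophil-like and macrophage-like clusters. Ftl1, the ferritin light chain, had a log2 ratio of 0.03 over all cells and was lower in 11 of 11 clusters. Log2 ratios were -0.06 for Tet2, 0.67 for Hmox1 (heme breakdown), 0.00 for Slc25a37 (mitochondrial iron import), -0.16 for Iscu (iron-sulfur scaffold) and -0.03 for Gpx4 (lipid peroxide repair), none past the 1.5-fold rule.

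**Figure D2:**
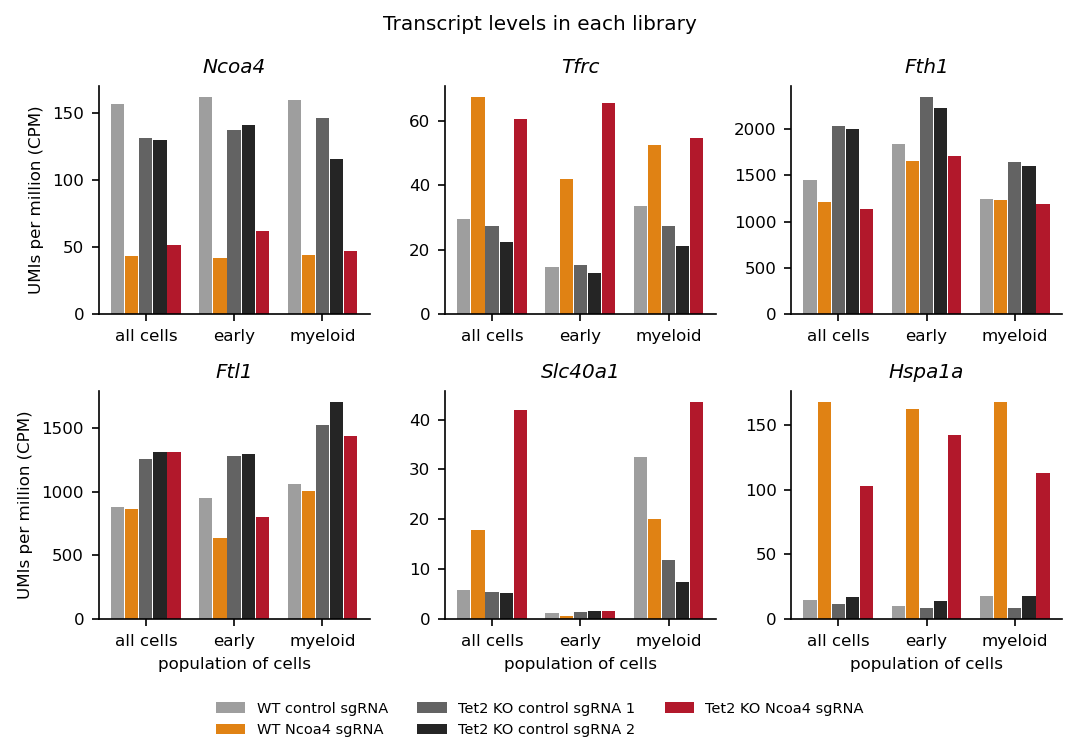
Levels of named transcripts (y axes, CPM) in the 5 libraries, for all cells, the early progenitor clusters and the myeloid progenitor-like class (x axes) as 1 bar per library, without error bars. Over all cells Tfrc stands at 60.6 and 67.4 CPM under Ncoa4 sgRNA and at 24.9 and 29.7 CPM under control sgRNA in Tet2 KO (mean) and WT.

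The genes most higher in Tet2 KO Ncoa4 were those of neutrophil granules and their neighbours: Camp (778-fold, 737 to 822), Ngp (662-fold, 629 to 697), Ltf (647-fold, 577 to 727) and Lcn2 (287-fold, 270.0 to 305). The calprotectin genes were S100a9 (539.8-fold, 525 to 555) and S100a8 (280.1-fold, 274 to 286), and the surface genes were Cd177 (305-fold, 240.0 to 393) and Ly6g (552-fold, 339 to 967). The other 4 were Retnlg (2833-fold, 1539.5 to 5909), Chil3 (401-fold, 361 to 447), Wfdc21 (178-fold, 161 to 197) and Ifitm6 (181-fold, 155 to 214). Neutrophil-like cells made up 29.9% of that library. The most lower genes included Mycn, a MYC family transcription factor, and the chemokine gene Ccl4. They were Mycn (14.8-fold, 10.7 to 20.97), Ccl4 (15.5-fold, 12.9 to 18.8), Ctla2a (11.9-fold, 11.0 to 12.8), Gimap1 (10.6-fold, 9.29 to 12.1), Gimap6 (10.5-fold, 9.27 to 12.1), Pdzk1ip1 (11.4-fold, 9.32 to 14.2) and Pglyrp2 (11.1-fold, 8.97 to 14.0), and H1fx (23.6-fold, 18.6 to 30.5), Pde1c (11.8-fold, 11.3 to 12.4) and Fah (10-fold, 9.003 to 11.1). H1fx, a linker histone, stood at 17.6 CPM in 1 control library and 122 in the other, against 3.06 in Tet2 KO Ncoa4. Pde1c stood at 605 and 1630.2 CPM and Fah at 86.5 and 229 in the control libraries. Gimap6 turned direction with class shares held at those of WT control, and Ly6g within the early clusters.

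Among the early progenitor clusters, the rule for named genes first gave Camp (811-fold, 403 to 1907), S100a9 (162-fold, 134 to 196), Ngp (240.2-fold, 159.7 to 375), S100a8 (42.8-fold, 36.8 to 49.8) and Ly6d (64.9-fold, 43.5 to 98.0), the last a marker of B lineage commitment. Empty droplets held S100a9 at 17211 CPM in this library against 86.2 and 77.5 CPM in the controls, so free RNA was not excluded for the neutrophil genes among these. The free RNA share estimated with these droplets, 2.73%, was itself set from neutrophil markers in early cells and cannot serve as a test, and the neutrophil genes in the myeloid progenitor-like class were not tested for free RNA either. Hspa1a, an inducible heat-shock chaperone, was 7.11-fold higher (95% interval 6.60 to 7.67) over all cells and higher in 11 of 11 clusters. The first lower genes there were Pde1c (9.34-fold, 7.99 to 11.0), Fah (9.07-fold, 6.04 to 14.3), Ccl3 (6.10-fold, 2.61 to 18.8) and Ccl4 (4.81-fold, 3.32 to 7.24). In the myeloid progenitor-like class the first higher genes were Camp (3249-fold, 899 to 26832), Jchain (at least 150.5-fold, with no UMI on the other side), Ngp (63.6-fold, 51.3 to 79.8) and Ltf (223-fold, 39.8 to 8839), and the first lower ones Pde1c (16.2-fold, 14.8 to 17.9), Fah (12.5-fold, 9.94 to 15.9), H1fx (10.6-fold, 6.23 to 19.1) and Slc22a3 (7.28-fold, 4.88 to 11.2). In this class Ngp stood at 41.1 and 0.439 CPM, H1fx at 7.92 and 41.2, Pde1c at 577 and 1697 and Fah at 78.7 and 223 in the 2 control libraries, a spread that the intervals do not cover.

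Of the 23 gene lists, the nuclear lists for OXPHOS, the respiratory chain, stood above expression-matched random lists and those for stem cell regulators, MHC and interferon response below. A list is given here by its median log2 ratio minus that of the random lists, its percentile among them, its members at least 1.5-fold higher and lower, and the log2 ratios of members at its extremes. Genes of iron uptake, storage and export lay at -0.05 (percentile 31.8), with 5 higher and 12 lower of 27, from Slc40a1 (2.76) and Tfrc (1.252) to Tfr2 (-2.14) and Pcbp1 (-1.54). Iron-sulfur cluster assembly genes lay at -0.06 (percentile 26.9), with 0 higher and 7 lower of 29, from Bola3 (0.08) and Isca2 (0.07) to Glrx5 (-1.83) and Fdxr (-0.98). Heme synthesis genes lay at 0.10 (percentile 75.6), with 1 higher and 2 lower of 16, from Alas1 (1.47) and Abcb10 (0.45) to Alad (-1.203) and Urod (-0.68). OXPHOS complex I genes lay at 0.45 (percentile 99.99), with 6 higher and 0 lower of 37, from Ndufv3 (0.94) and Ndufb7 (0.81) to Ndufv1 (-0.46) and Ndufs3 (-0.37). Nuclear genes of OXPHOS complexes II to V lay at 0.40 (percentile 99.9), with 4 higher and 1 lower of 42, from Cox7a2 (0.91) and Uqcrq (0.71) to Cox7a2l (-0.71) and Atp5k (-0.52). Mitochondrial-genome OXPHOS genes lay at -0.06 (percentile 38.9), with 0 higher and 1 lower of 13, from mt-Co3 (0.31) and mt-Cytb (0.08) to mt-Nd6 (-0.62) and mt-Nd3 (-0.57). TCA cycle genes lay at -0.05 (percentile 32.9), with 0 higher and 3 lower of 18, from Cs (-0.05) and Mdh2 (-0.06) to Suclg2 (-0.97) and Idh2 (-0.74). Glycolysis genes lay at 0.43 (percentile 99.2), with 2 higher and 5 lower of 19, from Slc16a3 (2.13) and Eno1 (0.66) to Pfkm (-1.84) and Pfkl (-1.09). The lists of complex I and complexes II to V stayed past the upper limit of percentiles under 22 of 22 and 20 of 22 alternatives.

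Ferroptosis defence and glutathione genes lay at -0.17 (percentile 8.93), with 3 higher and 11 lower of 23, from Gsr (1.68) and Gpx4 (-0.03) to Coq2 (-1.76) and Gch1 (-1.504). Lipid peroxidation and ferroptosis-promoting genes lay at 0.89 (percentile 100), with 6 higher and 3 lower of 12, from Alox5 (3.63) and Sat1 (1.42) to Fads2 (-1.86) and Fads1 (-1.56). Cholesterol synthesis genes lay at -0.02 (percentile 44.9), with 1 higher and 10 lower of 21, from Fdps (0.63) to Srebf2 (-1.28) and Sqle (-1.04). Autophagy and lysosome genes lay at 0.21 (percentile 99.3), with 2 higher and 11 lower of 46, from Hexa (0.66) and Ctsb (0.62) to Calcoco1 (-1.997) and Gabarapl1 (-1.33). Iron and 2-oxoglutarate dioxygenases lay at 0.03 (percentile 61.3), with 2 higher and 10 lower of 29, from Kdm7a (1.41) and P4hb (0.67) to Tet1 (-1.39) and Alkbh1 (-1.03). Integrated stress response genes lay at -0.09 (percentile 23.6), with 3 higher and 12 lower of 25, from Cebpb (1.26) and Mthfd2 (0.50) to Ddit4 (-2.43) and Phgdh (-0.89). Targets of p53 lay at -0.06 (percentile 33.1), with 2 higher and 11 lower of 24, from Bax (-0.05) and Ccng1 (-0.05) to Psrc1 (-1.46) and Sesn1 (-1.19). Lipid peroxidation genes, among them Tfrc, stood at 0.21 (percentile 91.7) within the early clusters, inside the limits. Pcbp1 stood at 130.1 and 577 CPM in the control libraries against 121 in Tet2 KO Ncoa4, and Glrx5 at 26.3 and 143 against 23.1, so that the lower values of both rest on control library 2. Gsr stood at 44.0 and 107 CPM and Coq2 at 23.6 and 81.8 in the control libraries. Glycolysis genes turned direction under 3 of 22 alternatives, to -0.27 (percentile 0.315) within the early clusters, -0.07 (percentile 22.7) within the myeloid progenitor-like class and -0.23 (percentile 2.45) with class shares of WT control. Within the early clusters autophagy genes turned to -0.05 (percentile 23.5). Dioxygenases, the enzyme class of Tet2, stood at 0.35 (percentile 100) within the early clusters.

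HSC quiescence and self-renewal regulators lay at -1.28 (percentile 0), with 1 higher and 28 lower of 32, from Gfi1 (0.76) and Fli1 (-0.07) to Mycn (-3.27). MYC-linked ribosome biogenesis genes lay at -0.32 (percentile 0.15), with 0 higher and 14 lower of 26, from Cad (-0.23) and Nolc1 (-0.26) to Myc (-1.94) and Odc1 (-1.38). S phase genes lay at -0.01 (percentile 43.8), with 1 higher and 10 lower of 43, from Rrm2 (0.996) and E2f8 (0.27) to Chaf1b (-1.21) and Ung (-1.19). G2 and M phase genes lay at 0.54 (percentile 100), with 4 higher and 2 lower of 53, from Ube2c (0.99) and Hmgb2 (0.85) to Psrc1 (-1.46) and Ctcf (-0.78). Type I interferon response genes lay at -0.32 (percentile 0.06), with 1 higher and 27 lower of 44, from Ifi27l2a (0.998) to Rtp4 (-2.11) and Gbp2 (-1.83). MHC class I and II genes lay at -0.61 (percentile 0), with 3 higher and 11 lower of 18, from H2-Eb1 (0.84) and Cd74 (0.74) to H2-Q6 (-1.94) and H2-Q7 (-1.67). NF-kB and inflammatory genes lay at 0.19 (percentile 90.7), with 8 higher and 10 lower of 25, from S100a9 (9.05) and S100a8 (8.12) to Ccl4 (-3.70) and Il1r1 (-2.28). Immediate early and dissociation genes lay at -0.08 (percentile 23.9), with 6 higher and 10 lower of 24, from Hspa1b (3.05) and Klf2 (2.94) to Dusp2 (-2.57) and Egr1 (-1.93). Within the early clusters HSC regulators stood at -0.28 (percentile 0.01) and NF-kB genes at -0.43 (percentile 0), while MHC genes at -0.12 (percentile 9.94), interferon genes at -0.09 (percentile 12.6) and MYC-linked genes at 0.08 (percentile 84.8) were inside the percentile limits. Integrated stress response genes stood at -0.37 (percentile 0.02) in the myeloid progenitor-like class. Odc1 stood at 40.2 and 116 CPM in the control libraries against 29.5 in Tet2 KO Ncoa4, and Ctcf at 84.2 and 161 against 71.1. With class shares held at those of WT control, these lists moved inside the limits: HSC regulators to -0.01 (percentile 44.6), G2 and M phase genes to 0.02 (percentile 60.7), MHC genes to -0.03 (percentile 36.6), MYC-linked genes to -0.12 (percentile 8.30), nuclear genes of complexes II to V to 0.07 (percentile 90.4), autophagy genes to 0.03 (percentile 67.2) and interferon genes to -0.03 (percentile 35.1).

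Of 7426 genes over the floor, 533 were at least 1.5-fold higher and 2025 lower, against 317 and 7 of 7331 between the 2 control libraries. The median log2 ratio of all genes was -0.39 and moved to 0.11 with TMM scaling, which gave 1352 higher and 596 lower and took the log2 ratio of Fth1 from -0.82 to -0.34, under 1.5-fold.

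The same contrast in WT cells asked whether the changes needed the loss of Tet2. Ncoa4 was 3.602-fold lower (95% interval 3.41 to 3.81), at 43.6 against 157 CPM, and lower in 16 of 16 clusters. Tfrc was 2.27-fold higher (95% interval 2.08 to 2.48), at 67.4 against 29.7 CPM, and higher in 16 of 16 clusters. Fth1 stood at 1213 against 1449.5 CPM, a log2 ratio of -0.26 that did not pass the rule, and was lower in 10 of 16 clusters. Slc40a1 stood at 17.8 against 5.82 CPM, under the floor. In the 2 myeloid progenitor-like clusters, the first with 252 of 610 cells in WT Ncoa4 and 100 of 182 in WT control, its ratio was 0.796 (0.587 to 1.09) and 0.948 (0.469 to 2.17), with intervals that include 1.

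Within the early progenitor clusters, Ncoa4 stood at 42.3 against 162 CPM, Tfrc at 41.8 against 14.6 CPM and Fth1 at 1648 against 1839 CPM. Ftl1 had a log2 ratio of -0.03 over all cells and was lower in 14 of 16 clusters. Log2 ratios were -0.12 for Tet2, -0.08 for Hmox1, -0.42 for Slc25a37, -0.12 for Iscu and 0.40 for Gpx4. Gpx4 was 1.54-fold higher (95% interval 1.42 to 1.67) in the myeloid progenitor-like class as a whole, whose mix of clusters differed.

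Neutrophil genes again led the higher genes, beside 9.97% of neutrophil-like cells: Ngp (200.2-fold, 183 to 219.9), Ltf (231-fold, 185 to 292), Camp (136.5-fold, 126 to 148), Lcn2 (67.1-fold, 60.6 to 74.4), S100a9 (168-fold, 159 to 177), S100a8 (94.0-fold, 90.4 to 97.7), Chil3 (161-fold, 128 to 204), Cd177 (134-fold, 83.4 to 229.7) and Ifitm6 (96.3-fold, 66.6 to 145). Retnlg, Ly6g and Syce1 had 2, 3 and 1 UMIs in WT control, and their ratios were Retnlg (1418-fold, 392 to 11707), Ly6g (257-fold, 87.7 to 1246) and Syce1 (864-fold, 155 to 34157). Syce1 stood at 0.0900 CPM or less outside WT Ncoa4. Il1rapl2, an interleukin receptor family gene, was the most lower (167-fold, 99.1 to 307). Dntt, the terminal transferase of early lymphoid cells, and the chemokine genes Ccl3 and Ccl4 followed among Dntt (8.60-fold, 7.90 to 9.37), Ccl3 (6.28-fold, 5.44 to 7.27), Ccl4 (6.06-fold, 5.49 to 6.71), Camk2b (9.39-fold, 8.08 to 11.0), Slc15a2 (9.04-fold, 7.53 to 10.9) and Pf4 (4.65-fold, 4.23 to 5.13). The rest were Ddit4 (4.67-fold, 4.17 to 5.25), Pglyrp2 (4.48-fold, 4.03 to 4.99), Fgf3 (4.80-fold, 4.09 to 5.65), Tbxa2r (4.13-fold, 3.53 to 4.85) and Gimap1 (3.65-fold, 3.39 to 3.94), among which Ddit4 encodes an inhibitor of mTOR signalling. Retnlg and Pf4 turned direction within the early clusters.

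In the early progenitor clusters the first higher genes were Syce1 (at least 181-fold, with no UMI on the other side), Ngp (44.0-fold, 22.05 to 103), Camp (68.1-fold, 26.3 to 252) and Hspa1b (22.1-fold, 17.1 to 29.0), with 0 UMIs of Syce1 in WT control there, and the first lower ones Il1rapl2 (45.0-fold, 24.9 to 90.6), Camk2b (6.95-fold, 5.44 to 9.003), Slc15a2 (7.16-fold, 5.14 to 10.2) and Ccl3 (5.11-fold, 4.17 to 6.32). Free RNA was not excluded for Ngp and Camp there, or for neutrophil genes in the myeloid progenitor-like class, since empty droplets held S100a9 at 4387 CPM in WT Ncoa4 against 97.53 CPM in WT control and the free RNA share was set from the same markers. Hspa1a was 11.2-fold higher (95% interval 10.01 to 12.6) over all cells and higher in 16 of 16 clusters. In the myeloid progenitor-like class the first higher genes were Syce1 (at least 30.3-fold, with no UMI on the other side), Chil3 (24.7-fold, 11.9 to 61.6), Car1 (22.5-fold, 6.17 to 187) and Hspa1b (11.6-fold, 7.82 to 18.0), and the first lower ones Camk2b (9.13-fold, 6.14 to 13.7), Bmi1 (4.25-fold, 2.96 to 6.08), Ncoa4 (3.63-fold, 3.15 to 4.18) and Gdf3 (3.61-fold, 2.99 to 4.36).

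Nuclear OXPHOS genes stood above the random lists in WT too, and MHC, interferon, cholesterol synthesis and HSC regulator genes below. Genes of iron uptake, storage and export lay at -0.03 (percentile 37.1), with 3 higher and 7 lower of 27, from Tfrc (1.16) and Pcbp1 (0.04) to Ncoa4 (-1.83) and Tfr2 (-1.27). Iron-sulfur cluster assembly genes lay at 0.04 (percentile 71.5), with 1 higher and 2 lower of 29, from Glrx5 (1.42) and Bola2 (0.42) to Fdxr (-0.71) and Ciao3 (-0.62). Heme synthesis genes lay at -0.01 (percentile 45.1), with 1 higher and 1 lower of 16, from Alas1 (0.69) and Tmem14c (0.43) to Alad (-0.64) and Slc25a39 (-0.55). OXPHOS complex I genes lay at 0.47 (percentile 100), with 4 higher and 0 lower of 37, from Ndufs6 (0.82) and Ndufb7 (0.71) to Ndufv1 (-0.43). Nuclear genes of OXPHOS complexes II to V lay at 0.43 (percentile 100), with 8 higher and 0 lower of 42, from Cox6a1 (0.80) and Uqcrq (0.71) to Atp5b (-0.41) and Sdha (-0.40). Mitochondrial-genome OXPHOS genes lay at 0.06 (percentile 68.5), with 1 higher and 0 lower of 13, from mt-Atp8 (0.79) and mt-Nd1 (0.55) to mt-Nd4l (-0.41) and mt-Nd6 (-0.32). TCA cycle genes lay at -0.13 (percentile 8.26), with 0 higher and 1 lower of 18, from Suclg1 (0.09) and Dlat (-0.05) to Idh3b (-0.63) and Idh2 (-0.58). Glycolysis genes lay at -0.01 (percentile 46.0), with 1 higher and 3 lower of 19, from Hk2 (0.21) and Slc2a3 (0.13) to Pfkl (-0.89) and Pfkm (-0.78). Complex I and complexes II to V stayed past the limit under 20 of 20 and 20 of 20 alternatives.

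Ferroptosis defence and glutathione genes lay at 0.13 (percentile 90.3), with 3 higher and 6 lower of 23, from Gsr (1.2504) and Gclm (0.72) to Cat (-0.82) and Keap1 (-0.77). Lipid peroxidation and ferroptosis-promoting genes lay at -0.04 (percentile 39.1), with 3 higher and 2 lower of 11, from Alox5 (1.67) and Tfrc (1.16) to Fads2 (-1.03) and Fads1 (-0.79). Cholesterol synthesis genes lay at -0.28 (percentile 0.14), with 0 higher and 11 lower of 21, from Fdps (0.19) and Ebp (0.06) to Insig1 (-1.06) and Dhcr7 (-0.92). Autophagy and lysosome genes lay at -0.04 (percentile 24.2), with 2 higher and 8 lower of 46, from Optn (1.31) to Calcoco1 (-1.11) and Gabarapl1 (-0.86). Iron and 2-oxoglutarate dioxygenases lay at 0.00 (percentile 49.1), with 0 higher and 4 lower of 29, from Kdm7a (0.48) and P4ha1 (0.16) to Riox1 (-0.72) and Egln2 (-0.69). Integrated stress response genes lay at 0.00 (percentile 49.1), with 3 higher and 7 lower of 24, from Cebpb (1.13) and Atf4 (0.23) to Ddit4 (-2.11) and Psat1 (-1.03). Targets of p53 lay at -0.15 (percentile 6.62), with 1 higher and 7 lower of 24, from Bax (0.18) and Ccng1 (-0.41) to Cdkn1a (-1.13) and Psrc1 (-0.86). Cholesterol synthesis stayed past the limit under 20 of 20 alternatives, and within the early clusters stood at -0.32 (percentile 0.12).

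HSC quiescence and self-renewal regulators lay at -0.44 (percentile 0), with 0 higher and 20 lower of 32, from Gfi1 (0.18) to Txnip (-1.55). MYC-linked ribosome biogenesis genes lay at 0.10 (percentile 86.9), with 0 higher and 1 lower of 26, from Srm (0.50) and Ncl (0.23) to Myc (-1.28) and Pes1 (-0.52). S phase genes lay at 0.02 (percentile 59.0), with 0 higher and 8 lower of 43, from Nasp (0.23) and E2f8 (0.23) to Chaf1b (-0.97) and Ung (-0.91). G2 and M phase genes lay at 0.13 (percentile 98.4), with 1 higher and 1 lower of 53, from Cks2 (0.62) and Hmgb2 (0.57) to Psrc1 (-0.86) and Tubb4b (-0.55). Type I interferon response genes lay at -0.29 (percentile 0), with 0 higher and 21 lower of 43, from Bst2 (0.10) and Ifitm3 (0.09) to Gbp2 (-1.33) and Oasl2 (-1.17). MHC class I and II genes lay at -0.52 (percentile 0), with 0 higher and 11 lower of 18, from B2m (0.37) and Nlrc5 (-0.09) to Cd74 (-1.42) and H2-Eb1 (-1.33). NF-kB and inflammatory genes lay at -0.17 (percentile 4.30), with 6 higher and 12 lower of 25, from S100a9 (7.37) and S100a8 (6.54) to Ccl4 (-2.501) and Ccl3 (-2.45). Immediate early and dissociation genes lay at -0.32 (percentile 0.09), with 6 higher and 10 lower of 23, from Hspa1b (3.599) and Hspa1a (3.40) to Zfp36 (-1.58) and Dusp2 (-1.53). Within the early clusters HSC regulators stood at -0.18 (percentile 2.07), NF-kB genes at -0.31 (percentile 0.18) and glycolysis genes at -0.33 (percentile 0.16), while MHC genes at -0.02 (percentile 41.3) and interferon genes at -0.11 (percentile 7.66) were inside the limits. Immediate early genes turned to 0.15 (percentile 93.5) in the myeloid progenitor-like class. G2 and M phase genes stayed past the limit under 17 of 20 alternatives and HSC regulators under 18 of 20. With class shares held at those of WT control, these lists moved inside the limits: HSC regulators to -0.02 (percentile 38.2), G2 and M phase genes to 0.07 (percentile 87.4), MHC genes to -0.19 (percentile 3.30), interferon genes to -0.02 (percentile 36.2) and immediate early genes to -0.05 (percentile 29.8).

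Of 7531 genes, 285 were higher and 1282 lower. WT had 1 control library, so no yardstick of this genotype existed, and 324 genes differed between those of Tet2 KO. TMM scaling moved the median log2 ratio from -0.24 to 0.09 and gave 790 higher and 313 lower genes.

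**Figure D3:**
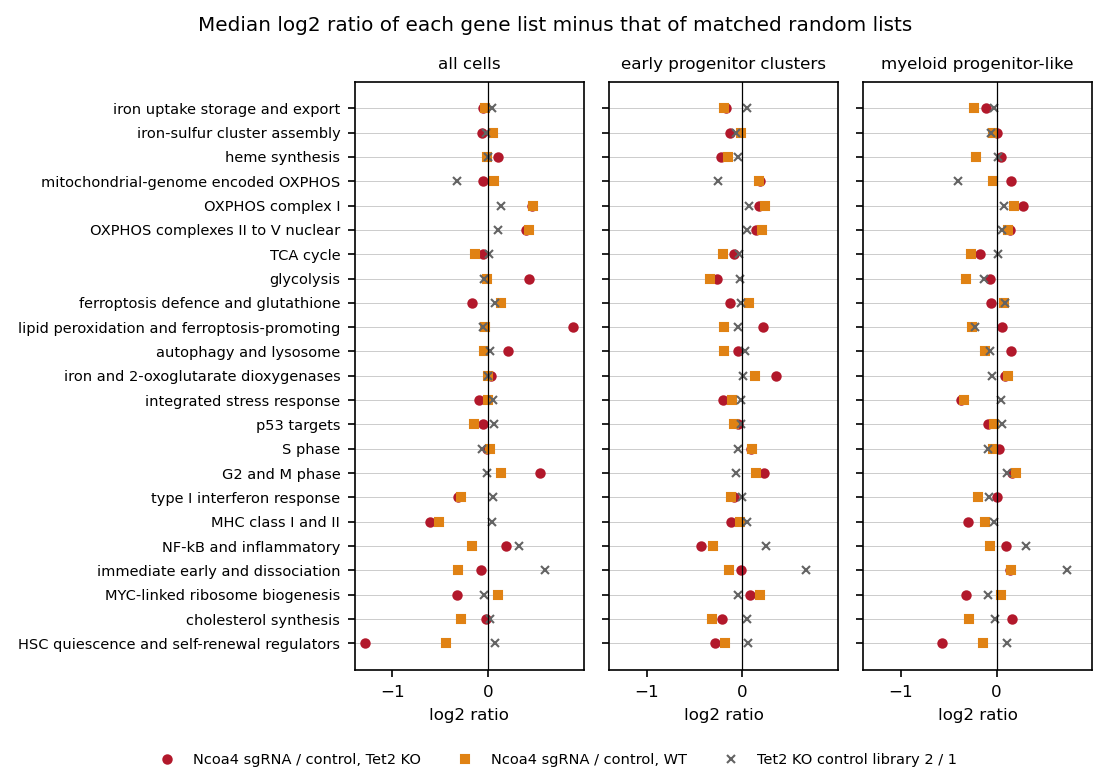
Median log2 ratio of each of 23 gene lists minus that of expression-matched random lists (x axis, log2) for Ncoa4 against control sgRNA in Tet2 KO and in WT, with the difference between the 2 Tet2 KO control libraries as crosses, in all cells and in 2 groups of clusters. In all cells OXPHOS complex I stands at 0.45 and 0.47, with the cross at 0.13.

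The Ncoa4 sgRNA differences in both genotypes, which share no library, were then set side by side. Tfrc was higher and Ncoa4 lower in both, and 204 genes were higher in both against 15.6 expected from the margins. Another 890 genes were lower in both against 323 expected, and 8 passed the rule in opposite directions. Neutrophil-like cells and higher Hspa1a in both Ncoa4 libraries were not set apart in these counts. With TMM scaling, most genes past the rule in either genotype were higher, not lower. Across 7168 genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.809 and a Spearman rho of 0.661. Within the early clusters r was 0.642, with 82 genes higher in both (7.17 expected) and 143 lower (31.3 expected), and within the myeloid progenitor-like class r was 0.438.

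The log2 effect was most positive in Tet2 KO relative to WT for Jchain, the immunoglobulin joining chain, and Il1b: Jchain (6.05), Il1b (3.31), Il1rapl2 (2.84), Aff2 (2.78), Ncam1 (2.72) and Camp (2.49). It was most negative for the meiotic gene Syce1 (-5.25), Slc25a21 (-4.37), Car1 (-3.55), H1fx (-3.50), Abcb4 (-3.25) and Glrx5 (-3.25). Their order depends on the 1 CPM added to each level, since Jchain stood at 0.151 and 0.111 CPM in the Tet2 KO controls, Il1b at 0.296 CPM in WT control, Il1rapl2 at 0.3003 and 0.585 CPM under Ncoa4 sgRNA in WT and Tet2 KO, and Syce1 at 0 to 0.0900 CPM outside WT Ncoa4. H1fx and Glrx5, an iron-sulfur cluster gene, differed by 2.73 and 2.40 between the 2 Tet2 KO control libraries. Less the random lists, HSC regulators differed by -0.60 (percentile 0) and MYC-linked genes by -0.36 (percentile 0), while G2 and M phase genes differed by 0.39 (percentile 100), NF-kB genes by 0.36 (percentile 99.95), glycolysis genes by 0.34 (percentile 99.8) and autophagy genes by 0.28 (percentile 100). The iron list differed by 0.22 (percentile 98.9) and complex I by 0.05 (percentile 76.3). Within the early clusters the differences were -0.05 (percentile 21) for HSC regulators, -0.10 (percentile 6.20) for MYC-linked genes, 0.18 (percentile 99.99) for G2 and M phase genes, 0.02 (percentile 58.9) for NF-kB genes, 0.03 (percentile 63.3) for glycolysis genes, 0.17 (percentile 99.8) for autophagy genes and 0.13 (percentile 94.2) for the iron list. Within the myeloid progenitor-like class they were, in the same order, -0.39 (percentile 0), -0.36 (percentile 0), -0.10 (percentile 4.75), 0.29 (percentile 98.0), 0.13 (percentile 89.7), 0.35 (percentile 100) and 0.07 (percentile 76.3). At least 1 log2 unit separated the effects for 537 genes, and none of these differences was tested.

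Tet2 KO and WT under control sgRNA were compared to show how the genotypes differed where Ncoa4 was not targeted. Slc25a21, a mitochondrial carrier, and Car1, an erythroid carbonic anhydrase, were most higher in Tet2 KO: Slc25a21 (10.5-fold, 9.06 to 12.3) and Car1 (5.19-fold, 4.85 to 5.56). Hmga2, an architectural chromatin protein, and Gclm, a subunit of the enzyme for glutathione synthesis, were also higher: Hmga2 (2.57-fold, 2.34 to 2.83) and Gclm (2.15-fold, 2.03 to 2.27). The other higher genes were Cenpv (4.45-fold, 3.79 to 5.27), Fam102b (3.85-fold, 3.37 to 4.41), Abcb4 (3.33-fold, 2.78 to 4.01) and Fam241a (2.82-fold, 2.44 to 3.26), and Cd59a (2.68-fold, 2.30 to 3.13), Ces2g (2.47-fold, 2.13 to 2.88), Ugcg (2.32-fold, 2.06 to 2.63) and Slc16a1 (2.24-fold, 1.93 to 2.62). Car1 stood at 142 and 301 CPM and Cenpv at 16.4 and 50.6 CPM in the 2 Tet2 KO libraries. The platelet chemokine gene Pf4, the chemokine gene Ccl3 and the nuclear noncoding RNA Neat1 were lower: Pf4 (2.39-fold, 2.22 to 2.57), Ccl3 (1.96-fold, 1.79 to 2.15) and Neat1 (2.04-fold, 1.97 to 2.12). Il1rapl2 and Auts2 led the other lower genes: Il1rapl2 (6.53-fold, 5.87 to 7.27), Auts2 (4.77-fold, 4.49 to 5.05), Hist1h2af (2.90-fold, 2.58 to 3.25) and Atrnl1 (2.78-fold, 2.58 to 3.003), and Slc15a2 (2.78-fold, 2.49 to 3.11), Fndc3b (2.08-fold, 1.94 to 2.23), Nrg2 (2.08-fold, 1.89 to 2.28), Camk2d (2.04-fold, 1.89 to 2.21) and Cers6 (1.98-fold, 1.88 to 2.09).

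Ncoa4 stood at 131 against 157 CPM, Tfrc at 24.9 against 29.7 CPM and Fth1 at 2012 against 1449.5 CPM in Tet2 KO against WT. Log2 ratios were 0.47 for Fth1, 0.54 for Ftl1, -0.11 for Slc40a1, -0.03 for Hmox1, -0.50 for Slc25a37, 0.39 for Iscu and 0.58 for Gpx4. Tet2 itself had a log2 ratio of -0.28, and counts of transcript 5' ends do not show whether exons were deleted. Direction turned for Ces2g and Nrg2 with class shares held at those of WT control, for Abcb4 in the myeloid progenitor-like class, and for Slc25a21 and Pf4 in the early clusters.

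Complex I and iron-sulfur cluster genes stood above the random lists, and G2 and M phase genes and p53 targets below. Genes of iron uptake, storage and export lay at -0.07 (percentile 11.4), with 2 higher and 0 lower of 26, from Pcbp1 (1.51) and Slc25a28 (1.10) to Trf (-0.52) and Slc25a37 (-0.50). Iron-sulfur cluster assembly genes lay at 0.21 (percentile 99.9), with 1 higher and 0 lower of 29, from Glrx5 (1.92) and Fdx2 (0.46) to Ndor1 (-0.34). Heme synthesis genes lay at 0.03 (percentile 65.0), with 0 higher and 0 lower of 16, from Tmem14c (0.39) and Urod (0.24) to Alas1 (-0.52) and Abcb10 (-0.23). OXPHOS complex I genes lay at 0.22 (percentile 99.9), with 0 higher and 0 lower of 37, from Ndufa8 (0.44) and Ndufs7 (0.43) to Ndufs1 (-0.18) and Ndufa3 (-0.18). Nuclear genes of OXPHOS complexes II to V lay at 0.08 (percentile 92.6), with 0 higher and 0 lower of 42, from Sdhc (0.43) and Atp5g3 (0.42) to Atp5mpl (-0.25) and Sdha (-0.21). Mitochondrial-genome OXPHOS genes lay at -0.12 (percentile 9.76), with 1 higher and 0 lower of 13, from mt-Atp8 (1.15) and mt-Nd1 (0.14) to mt-Nd3 (-0.55) and mt-Nd4l (-0.40). TCA cycle genes lay at -0.03 (percentile 31.6), with 0 higher and 0 lower of 18, from Suclg1 (0.22) and Mdh1 (0.10) to Ogdh (-0.37) and Dld (-0.25). Glycolysis genes lay at -0.07 (percentile 17.8), with 1 higher and 1 lower of 19, from Slc16a1 (1.09) and Ldhb (0.10) to Eno1 (-0.73) and Gpi1 (-0.45). Pcbp1 stood at 130.1 and 577 CPM, Glrx5 at 26.3 and 143 and Slc25a28 at 14.1 and 41.5 in the 2 Tet2 KO libraries.

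Ferroptosis defence and glutathione genes lay at 0.10 (percentile 91.5), with 3 higher and 0 lower of 23, from Coq2 (1.30) and Gclm (1.08) to Gss (-0.34) and Slc3a2 (-0.33). Lipid peroxidation and ferroptosis-promoting genes lay at -0.11 (percentile 6.95), with 0 higher and 1 lower of 11, from Sat1 (0.16) and Por (-0.06) to Elovl5 (-0.57) and Lpcat3 (-0.39). Cholesterol synthesis genes lay at -0.05 (percentile 18.5), with 0 higher and 0 lower of 21, from Pmvk (0.30) and Ebp (0.20) to Dhcr7 (-0.37). Autophagy and lysosome genes lay at -0.07 (percentile 3), with 2 higher and 0 lower of 46, from Lamp1 (1.85) and Gabarap (0.35) to Atg7 (-0.40) and Ctsb (-0.38). Iron and 2-oxoglutarate dioxygenases lay at -0.08 (percentile 4.71), with 0 higher and 0 lower of 29, from Alkbh1 (-0.03) and Kdm5c (-0.04) to P4hb (-0.54) and Phf8 (-0.46). Integrated stress response genes lay at 0.03 (percentile 68.7), with 2 higher and 1 lower of 24, from Cebpb (0.83) and Ddit4 (0.10) to Slc3a2 (-0.33) and Aars (-0.31). Targets of p53 lay at -0.15 (percentile 0.27), with 1 higher and 2 lower of 24, from Bax (0.34) and Dcxr (0.25) to Cdkn1a (-0.40) and Mdm2 (-0.36). Lamp1 stood at 27.8 and 172 CPM and Coq2 at 23.6 and 81.8 in the 2 Tet2 KO libraries.

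HSC quiescence and self-renewal regulators lay at -0.01 (percentile 41.6), with 2 higher and 0 lower of 32, from Nr4a2 (0.75) to Bmi1 (-0.58) and Runx1 (-0.55). MYC-linked ribosome biogenesis genes lay at 0.02 (percentile 59.8), with 1 higher and 0 lower of 26, from Odc1 (1.01) and Srm (0.41) to Utp20 (-0.37) and Mybbp1a (-0.30). S phase genes lay at -0.04 (percentile 17.2), with 0 higher and 0 lower of 43, from Gins2 (0.34) and Gmnn (0.17) to Rrm2 (-0.51) and Brip1 (-0.51). G2 and M phase genes lay at -0.20 (percentile 0), with 0 higher and 0 lower of 53, from Ctcf (0.57) and Cks1b (0.31) to G2e3 (-0.53) and Nek2 (-0.53). Type I interferon response genes lay at 0.06 (percentile 89.5), with 0 higher and 0 lower of 44, from Ifitm3 (0.47) and Rtp4 (0.45) to Gbp3 (-0.44) and Lgals3bp (-0.36). MHC class I and II genes lay at -0.08 (percentile 11.5), with 0 higher and 0 lower of 18, from B2m (0.52) and H2-DMa (0.31) to H2-Eb1 (-0.52) and Cd74 (-0.48). NF-kB and inflammatory genes lay at 0.05 (percentile 79.7), with 2 higher and 1 lower of 24, from Cebpb (0.83) and S100a9 (0.17) to Ccl3 (-0.95) and Zfp36 (-0.45). Immediate early and dissociation genes lay at -0.16 (percentile 0.14), with 1 higher and 1 lower of 24, from Dusp2 (0.40) and Ier3 (0.22) to Dusp1 (-0.45) and Zfp36 (-0.45). Odc1 stood at 40.2 and 116 CPM, Cebpb at 35.0 and 67.4, Nr4a2 at 16.2 and 32.0 and Bmi1 at 9.10 and 21.3 in the 2 Tet2 KO libraries. Between the 2 Tet2 KO control libraries immediate early genes differed by 0.59 (percentile 100) and complex I genes by 0.13 (percentile 100). In the myeloid progenitor-like class these lists moved inside the limits: G2 and M phase genes to 0.00 (percentile 45.7), complex I genes to 0.02 (percentile 69.8), immediate early genes to 0.05 (percentile 73), iron-sulfur cluster genes to 0.05 (percentile 80.4) and p53 targets to -0.04 (percentile 33.2). Complex I, iron-sulfur cluster and G2 and M phase genes and p53 targets stayed past the limits under 21 of 22, 20 of 22, 21 of 22 and 19 of 22 alternatives. Immediate early genes did so under 17 of 22 and turned direction under 2, in the myeloid progenitor-like class and, to 0.13 (percentile 93.3), without library 1.

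Of 7507 genes, 40 were higher and 54 lower. TMM scaling moved the median log2 ratio from -0.14 to -0.02 and gave 59 higher and 27 lower genes. With only 1 Tet2 KO library in the comparison, 589 genes passed without library 1 and 128 without library 2, beside 324 between the 2 Tet2 KO libraries. The genes most higher in library 2 by the log2 ratio of CPM plus 1 were Hras (13.4-fold), Sap30l (11.7-fold), Ptp4a1 with ID ENSMUSG00000117310 (11.9-fold), Srsf9 (9.04-fold), Zmynd19 (8.56-fold) and Mtch1 (7.41-fold).

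Tet2 KO and WT under Ncoa4 sgRNA were compared to ask how the genotypes differed once Ncoa4 was targeted. Il1b, the cytokine interleukin-1 beta, was most higher in Tet2 KO: Il1b (18.3-fold, 14.6 to 23.02). Neutrophil genes were higher beside a share of neutrophil-like cells of 29.9% against 9.97%: Camp (3.65-fold, 3.62 to 3.67), S100a9 (3.61-fold, 3.598 to 3.62), Lcn2 (3.58-fold, 3.55 to 3.62), Mmp9 (3.68-fold, 3.44 to 3.95), Lrg1 (3.90-fold, 3.68 to 4.14), Chil1 (3.82-fold, 3.58 to 4.08) and Orm1 (3.86-fold, 3.54 to 4.20). The other higher genes were Camk2b (6.49-fold, 5.56 to 7.61), Jchain (4.59-fold, 4.22 to 5.003), Ccl5 (4.31-fold, 3.74 to 4.98) and Clec4a2 (3.58-fold, 3.39 to 3.77), of which Ccl5 encodes a chemokine. The stem cell transcription factor genes Mecom (5.10-fold, 4.58 to 5.70) and Hoxa9 (4.40-fold, 3.83 to 5.08) and Angpt1 (4.07-fold, 3.90 to 4.24), a ligand of the Tie2 receptor, were lower. Prg2 (8.40-fold, 7.21 to 9.85), which encodes eosinophil major basic protein, and Tgfbr3 (4.42-fold, 3.93 to 4.98), a co-receptor for TGF-beta, were lower too. The other lower genes were Auts2 (9.81-fold, 8.92 to 10.8), Gnb4 (8.92-fold, 7.24 to 11.1), Prkg1 (4.56-fold, 4.17 to 4.98), Slc22a3 (4.50-fold, 4.12 to 4.93), Samd12 (5.07-fold, 4.13 to 6.30) and Mdga1 (4.63-fold, 4.04 to 5.33). Syce1 had 2 UMIs in Tet2 KO, and its ratio to WT was Syce1 (474-fold, 131 to 3913.5).

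Ncoa4 stood at 51.8 against 43.6 CPM, Tfrc at 60.6 against 67.4 CPM, Fth1 at 1139 against 1213 CPM and Slc40a1 at 41.9 against 17.8 CPM in Tet2 KO against WT. Ftl1 was 1.52-fold higher (95% interval 1.502 to 1.55). Log2 ratios were -0.22 for Tet2, 0.72 for Hmox1, -0.08 for Slc25a37, 0.35 for Iscu and 0.15 for Gpx4. Class shares held at those of WT control turned the direction of Ccl5, Mecom, Prkg1, Samd12 and Angpt1. Ccl5 and Prg2 turned in the myeloid progenitor-like class, and Il1b, Ccl5, Chil1, Orm1 and Tgfbr3 in the early clusters, where Tet2 KO Ncoa4 had 101 cells.

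NF-kB, glycolysis and autophagy genes stood above the random lists, and MYC-linked genes and HSC regulators below. Genes of iron uptake, storage and export lay at 0.11 (percentile 87.3), with 4 higher and 6 lower of 27, from Slc40a1 (1.19) and Ftl1 (0.61) to Tfr2 (-1.18) and Trf (-0.65). Iron-sulfur cluster assembly genes lay at 0.10 (percentile 88.0), with 0 higher and 2 lower of 29, from Isca2 (0.41) and Iscu (0.35) to Glrx5 (-1.32) and Bola2 (-0.68). Heme synthesis genes lay at 0.22 (percentile 97.4), with 0 higher and 0 lower of 16, from Alas1 (0.26) and Tmem14c (0.25) to Alad (-0.43) and Clpx (-0.27). OXPHOS complex I genes lay at 0.12 (percentile 93.6), with 0 higher and 0 lower of 37, from Ndufv3 (0.38) and Ndufb3 (0.33) to Ndufa3 (-0.47) and Ndufa12 (-0.33). Nuclear genes of OXPHOS complexes II to V lay at 0.02 (percentile 60.4), with 0 higher and 1 lower of 42, from Uqcrb (0.30) and Cox5a (0.28) to Atp5k (-0.90) and Atp5mpl (-0.50). Mitochondrial-genome OXPHOS genes lay at -0.21 (percentile 3.50), with 0 higher and 2 lower of 13, from mt-Nd4l (0.06) and mt-Atp8 (0.02) to mt-Nd3 (-1.34) and mt-Atp6 (-0.67). TCA cycle genes lay at -0.01 (percentile 46.5), with 0 higher and 1 lower of 18, from Mdh2 (0.06) and Dld (-0.05) to Suclg2 (-0.70) and Idh2 (-0.38). Glycolysis genes lay at 0.30 (percentile 99.8), with 1 higher and 2 lower of 19, from Slc16a3 (1.24) and Slc2a3 (0.49) to Hk1 (-0.67) and Slc2a1 (-0.51).

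Ferroptosis defence and glutathione genes lay at 0.03 (percentile 63.1), with 2 higher and 2 lower of 23, from Gsr (0.62) and Gclm (0.28) to Sod1 (-0.54) and Coq2 (-0.54). Lipid peroxidation and ferroptosis-promoting genes lay at 0.03 (percentile 59.5), with 5 higher and 3 lower of 12, from Alox5 (1.27) and Sat1 (0.85) to Por (-0.64) and Acsl4 (-0.39). Cholesterol synthesis genes lay at 0.21 (percentile 98.0), with 0 higher and 1 lower of 21, from Fdps (0.55) and Ebp (0.10) to Srebf2 (-0.60) and Hmgcs1 (-0.30). Autophagy and lysosome genes lay at 0.21 (percentile 99.9), with 2 higher and 3 lower of 46, from Gabarap (0.71) and Atp6v0d1 (0.54) to Pink1 (-0.68) and Atg13 (-0.54). Iron and 2-oxoglutarate dioxygenases lay at -0.09 (percentile 10.1), with 1 higher and 5 lower of 29, from Kdm7a (0.87) and Kdm6b (0.29) to Tet1 (-0.96) and Fto (-0.88). Integrated stress response genes lay at 0.05 (percentile 69.3), with 3 higher and 5 lower of 24, from Cebpb (0.96) and Mthfd2 (0.33) to Slc7a5 (-0.88) and Aldh18a1 (-0.59). Targets of p53 lay at 0.02 (percentile 59.99), with 2 higher and 6 lower of 24, from Ccng1 (0.17) and Bax (0.12) to Sesn1 (-0.96) and Ei24 (-0.48).

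HSC quiescence and self-renewal regulators lay at -0.65 (percentile 0), with 0 higher and 20 lower of 32, from Gfi1 (0.14) to Hoxa9 (-2.03) and Gata2 (-1.81). MYC-linked ribosome biogenesis genes lay at -0.38 (percentile 0), with 0 higher and 11 lower of 26, from Pes1 (-0.21) and Nop16 (-0.35) to Gnl3 (-0.87) and Myc (-0.83). S phase genes lay at -0.11 (percentile 4.22), with 0 higher and 2 lower of 43, from Rrm2 (0.55) and Gmnn (0.20) to Pola1 (-0.75). G2 and M phase genes lay at 0.10 (percentile 95.1), with 1 higher and 2 lower of 53, from Ube2c (0.67) and Cdca3 (0.42) to Cbx5 (-0.68) and G2e3 (-0.44). Type I interferon response genes lay at 0.15 (percentile 98.0), with 5 higher and 6 lower of 43, from Ifi27l2a (1.09) and Ifitm3 (0.42) to Lgals3bp (-1.01) and Gbp7 (-0.72). MHC class I and II genes lay at -0.20 (percentile 2.02), with 5 higher and 7 lower of 18, from Cd74 (1.68) and H2-Eb1 (1.64) to H2-Q6 (-1.30) and H2-Q7 (-1.18). NF-kB and inflammatory genes lay at 0.47 (percentile 100), with 7 higher and 4 lower of 25, from Il1b (3.62) and Ccl5 (1.94) to Tnfaip3 (-1.54) and Nfkb1 (-0.30). Immediate early and dissociation genes lay at -0.19 (percentile 1.51), with 3 higher and 7 lower of 23, from Klf2 (0.89) and Ier5 (0.77) to Fosb (-1.28) and Jun (-0.88). MYC-linked genes stayed past the limit under 20 of 20 alternatives, while NF-kB genes turned to -0.09 (percentile 10.9) and glycolysis genes to -0.16 (percentile 0.5) in the early clusters. HSC regulators stood at -0.07 (percentile 7.97) there, inside the limits. With class shares held at those of WT control, these lists moved inside the limits: HSC regulators to -0.08 (percentile 9.95), MHC genes to -0.10 (percentile 4.75), autophagy genes to 0.08 (percentile 93), interferon genes to -0.08 (percentile 10.7), immediate early genes to -0.10 (percentile 4.75), NF-kB genes to -0.18 (percentile 2.88), cholesterol synthesis genes to 0.01 (percentile 52.95) and glycolysis genes to -0.02 (percentile 37.0).

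Of 6875 genes, 355 were higher and 1008 lower. TMM scaling moved the median log2 ratio from -0.22 to 0.06 and gave 764 higher and 385 lower.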

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

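The tests on neutrophil-like cells and those of a different mix of cell classes were chosen only after the results were seen, as were the alternatives without the GC trend and within the early progenitor clusters.

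Neutrophil-like cells made up 29.9% of Tet2 KO Ncoa4 and 9.97% of WT Ncoa4 cells, against 1 control cell, and S100a9 reached 41272 and 11432 CPM over all cells. Free RNA or doublets with early progenitors would carry Cd34, but it stood at 0.799% (0.547 to 1.13) of its level over all other cells. This level pools all libraries, of which Tet2 KO Ncoa4 had Cd34 at 110 CPM, against 3.56 in neutrophil-like cells. Myeloid progenitor-like cells have less Cd34, and their RNA or doublets were not excluded, with Elane at 19.0% and Mpo at 4.43%. Cells from outside the gate are a candidate cause, with Kit at 11.5% (10.2 to 12.9) and Ly6a at 3.86% (1.995 to 6.76) of those pooled levels. A shift toward the neutrophil lineage under Ncoa4 sgRNA stays open and was not tested. Nor was the gate excluded for other class shares. Ly6a, used to pick early clusters, stood at 9.43 and 5.03 CPM in myeloid progenitor-like clusters against 32.6 in all cells. The gate selects Kit and Sca1 protein, which transcript levels do not show.

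Tfrc was higher under Ncoa4 sgRNA by 2.45-fold in Tet2 KO and 2.27-fold in WT. A different mix of classes was argued against, because with class shares held at those of WT control the lower of both ratios was 2.18, in WT, with 2.61 in Tet2 KO. In the same order, the ratios were 2.23 and 2.37 after subtraction of free RNA and 2.21 and 2.42 after removal of the GC trend. An effect of targeting Ncoa4 was not tested apart from these. Nor was a difference in handling between the sgRNA arms, along which Hspa1a differed by 7.11-fold and 11.2-fold. Both stay open.

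Between the 2 Tet2 KO control libraries, 317 genes were higher in library 2 and 7 lower, and 225 of the higher ones were at least 1.5-fold above every other library. GC content of whole transcripts was argued against, with a Spearman rho of 0.0152 across genes and 323 genes apart after its removal, as were depth, with 353 genes apart in thinned cells, and the mix of classes, with 365 apart within the early progenitor clusters. GC content of the first 200 transcript bases is a candidate explanation of a part: its median was 63% over all genes and 76.5% in the higher genes, which lies at percentile 92.8 of all genes, and 139 of the 367 genes in the highest of 20 bins were higher. Across all genes its Spearman rho was 0.125, against -0.201 for transcript length, and 247 of the 317 higher genes stayed so after removal of its trend, which argues against it as the whole cause. Explanation and trend removal were both thought of after earlier results had been seen, and no biological explanation was tested, since both libraries carry the same group label.

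Genes past the size rule in opposite directions under Ncoa4 sgRNA in Tet2 KO and WT had these untested differences of log2 ratios, Tet2 KO minus WT: Car1 (-3.55), Nfia (-2.04), Abcb4 (-3.25), Tgfbr3 (-2.32), Ces2g (-2.29) and Slc25a21 (-4.37) were more negative in Tet2 KO. H2-Eb1 (2.17) and Cd74 (2.16), which encode parts of MHC class II antigen presentation, were more positive. Cells of the clusters that these genes lead differed too, in the order WT control, WT Ncoa4, Tet2 KO control 1, Tet2 KO control 2 and Tet2 KO Ncoa4: 0.180%, 4.80%, 2.68%, 1.51% and 1.01% for the cluster of Slc25a21, Nfia and Abcb4, 0.898%, 1.76%, 1.32%, 4.64% and 1.37% for that of Car1 and Ces2g, 3.23%, 6.32%, 4.67%, 0.635% and 1.37% for that of Tgfbr3 and 1.08%, 0.777%, 1.245%, 1.32% and 2.21% for that of Cd74 and H2-Eb1. A different mix of cells was not excluded for these genes. In barcodes outside the cells, which entered only the free RNA estimates, the beta-globin gene Hbb-bs lay above its level in the control libraries: it stood at 32.5 CPM in WT Ncoa4 and 191 CPM in Tet2 KO Ncoa4, against 1.58 to 4.37 CPM in the controls.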

How the results depend on the processing

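The alternatives within single groups of clusters, without neutrophil-like and macrophage-like clusters, with another free RNA profile, without the top doublet scores and without the GC trend were chosen after seeing the data. No paired analysis was possible because the labels link no library of a group to one of another group. The counts of genes past the size rule were 2558 (Ncoa4 in Tet2 KO), 1567 (Ncoa4 in WT), 94 (genotype under control), 1363 (genotype under Ncoa4) and 537 (difference of effects), and elsewhere stayed within 1.5 times these values. Fewer or more genes enter by construction with the CPM filter. In the same order, the counts at 5 CPM were 4251, 2587, 219, 2414 and 924. At 50 CPM they were 1245, 818, 48, 691 and 283, and without the filter 5421, 3146, 334, 3150 and 1120. With class shares of WT control they were 865, 839, 58, 705 and 188 in the same order, and in thinned cells 2049 (genotype under Ncoa4). Within the myeloid progenitor-like class they were 612 (Ncoa4 in Tet2 KO), 775 (Ncoa4 in WT), 381 (genotype under Ncoa4) and 186 (difference of effects). Within the early progenitor clusters they were 603, 984, 62, 278 and 82, in the order of the first counts. Without neutrophil-like and macrophage-like clusters they were 1615 (Ncoa4 in Tet2 KO), 886 (genotype under Ncoa4) and 310 (difference of effects). The cause of these changes was not tested. Leaving out each Tet2 KO control library in turn gave 128 to 589 genes for genotype under control, the highest without library 1. With class shares of WT control, 52.5% (Ncoa4 in Tet2 KO) and 65.8% (genotype under Ncoa4) of the genes were higher. TMM scaling left the counts at 1948, 1103, 86 and 1149, of which 1129, 598, 65 and 728 were the same genes, and turned the share of higher genes from 20.8%, 18.2%, 42.6% and 26.0% to 69.4%, 71.6%, 68.6% and 66.5%.

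Shares of cells changed as follows, and the cause was not tested. Clustering of thinned cells gave neutrophil-like shares of 11.6% (WT Ncoa4) and 32.6% (Tet2 KO Ncoa4) and HSC-like shares of 14.4% (WT control), 2.06% (WT Ncoa4), 23.3% (Tet2 KO control 1) and 28.4% (Tet2 KO control 2). Resolution 0.5 gave neutrophil-like shares of 12.2% (WT Ncoa4) and 35.6% (Tet2 KO Ncoa4) and HSC-like shares of 4.63% (WT control), 7.71% (WT Ncoa4), 19.0% (Tet2 KO control 2) and 1.49% (Tet2 KO Ncoa4). Resolution 1.5 gave HSC-like shares of 1.53% (WT control), 8.17% (Tet2 KO control 1) and 10.9% (Tet2 KO control 2). The use of 20 principal components gave neutrophil-like shares of 12% (WT Ncoa4) and 34.8% (Tet2 KO Ncoa4) and HSC-like shares of 2.20% (WT control), 10.2% (Tet2 KO control 1) and 13.8% (Tet2 KO control 2). A cell minimum raised 2-fold gave neutrophil-like shares of 8.90% (WT Ncoa4) and HSC-like shares of 2.23% (WT control), 0.397% (WT Ncoa4), 7.60% (Tet2 KO control 1) and 10.1% (Tet2 KO control 2). A lowered cell minimum gave neutrophil-like shares of 12.5% (WT Ncoa4) and 33.7% (Tet2 KO Ncoa4) and HSC-like shares of 8.63% (WT control), 7.43% (WT Ncoa4), 19.0% (Tet2 KO control 1), 26.3% (Tet2 KO control 2) and 1.54% (Tet2 KO Ncoa4). A mitochondrial share under 5% gave neutrophil-like shares of 13.5% (WT Ncoa4) and 37.5% (Tet2 KO Ncoa4) and HSC-like shares of 2.24% (WT control), 7.53% (WT Ncoa4), 9.67% (Tet2 KO control 1), 12.9% (Tet2 KO control 2) and 1.57% (Tet2 KO Ncoa4). Removal of marked doublets gave HSC-like shares of 0.809% (WT control), 0.609% (WT Ncoa4), 6.74% (Tet2 KO control 1) and 9.42% (Tet2 KO control 2). In every alternative, neutrophil-like cells were more frequent under Ncoa4 than under control sgRNA in both genotypes. Over these 8 alternatives, in the order WT control, WT Ncoa4, Tet2 KO control 1, Tet2 KO control 2 and Tet2 KO Ncoa4, myeloid progenitor-like shares lay at 4.46% to 15.05%, 17.0% to 39.1%, 4.32% to 11.1%, 4.20% to 8.64% and 23.9% to 47.7%, higher under Ncoa4 sgRNA in each. Lymphoid-primed shares lay at 5.71% to 11.3%, 0.203% to 1.19%, 3.89% to 8.21%, 4.004% to 7.56% and 0.165% to 1.05%, lower under Ncoa4 sgRNA in each of the 7 that had such a cluster, and resolution 0.5 had none. Early progenitor shares lay at 46.8% to 53.8%, 17.0% to 24.6%, 57.5% to 65.4%, 58.3% to 67.4% and 4.02% to 6.80%, lower under Ncoa4 sgRNA in each.

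Over all alternatives, the log2 ratio of Ncoa4 lay at -1.54 to -0.84 in Tet2 KO and -1.91 to -1.51 in WT, that of Tfrc at 1.12 to 2.16 and 0.63 to 1.47, and that of Fth1 at -0.93 to -0.34 and -0.28 to 0.06. Slc40a1 lay at 0.08 to 3.22 and -0.67 to 2.04, Ftl1 at -0.69 to 0.52 and -0.58 to 0.29, and Hmox1 at -1.14 to 1.57 and -0.75 to 0.87. In Tet2 KO against WT under Ncoa4 sgRNA, interferon genes stayed past the limits under 8, cholesterol synthesis under 11 and MHC genes under 12 of 20 alternatives. Lists past the limits turned direction as follows: Ncoa4 in Tet2 KO, MYC-linked genes under 1, autophagy genes under 1, glycolysis genes under 3 and interferon genes under 1 of 22; Ncoa4 in WT, immediate early genes under 1 of 20; genotype under control, immediate early genes under 2 of 22; genotype under Ncoa4, NF-kB genes under 3, glycolysis genes under 2 and interferon genes under 3 of 20. Among the populations used for gene comparisons, depth limits the early progenitor clusters of Tet2 KO Ncoa4 most, with 101 cells, where 0 UMIs allow up to 2.43 CPM.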

Other observations

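The erythroid membrane genes Ermap, Kel and Rhag marked a cluster led by Slc25a21, Nfia and Abcb4. Its shares, and the order of libraries used here, are given above. A cluster led by Cdk8 and Filip1l, with Gm42418 at 20089 CPM, made up 1.03%, 9.90%, 1.67%, 1.81% and 1.61%. Syce1, also among its leading genes, had UMIs in early cells of WT Ncoa4 only. Dendritic cell-like cells, the cluster of Cd74 and H2-Eb1 above, also had the B lineage genes Ebf1, Cd79a and Igll1 among their leading genes. T or NK cell-like cells numbered 2, 5, 0, 0 and 14.

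Gm42418, Hspa1a and Hspa1b differed along the sgRNA in both genotypes. Gm42418, a gene model outside the named-gene rule that was chosen after its values were seen, and that overlaps ribosomal RNA repeats, stood at 9699 against 4837 CPM for Ncoa4 against control sgRNA in Tet2 KO and 14019 against 4166 CPM in WT, and was higher in 11 of 11 and 16 of 16 clusters. Hspa1a, the heat-shock chaperone, stood at 103 against 14.4 CPM and 168 against 14.98 CPM, and Hspa1b, whose sequence is nearly the same, at 92.1 against 10.3 CPM and 133 against 10.1 CPM. No explanation of these differences was tested.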
